A study of Mus musculus with 4 samples.

How the data were processed

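Total RNA from mouse quadriceps was extracted with Trizol, cleaned on columns with DNase treatment, labelled with biotin as cRNA and hybridised to Illumina Ref-8 arrays, per the labels' protocols. The deposited values are linear intensities with 1 row per gene symbol. The values themselves show that the authors had normalized them between arrays, since values of equal rank differ by a median of 0.092% between arrays, and that background was not subtracted, the lowest value being 72.8. The software and the way probes were summarised per gene are not given in the sources used here. A second table of signals and detection p-values was not used, because its 8 value columns carry names that match no sample label. Without detection p-values, the planned neqc correction was replaced by the deposited intensities, and the planned detection filter by a signal level.

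The table held 18091 rows. Of their symbols, 14090 are current, 3044 were matched to a current symbol through an older name, 75 matched several and 882 matched none and kept the name of the file. Where rows shared a symbol the row with the highest mean was used, leaving 17906 genes. Background was taken as the mode of all log2 values, 84.9, with an SD of 0.05 on the log2 scale from the values below the mode. A gene was tested if it exceeded 90.3 (the mode plus 1.645 SD) on at least 2 of the 4 arrays. This assumes that most genes are not expressed, and it was set after the data were examined.

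Lin28a transgenic was compared with wild type on log2 intensity with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Python 3.11.15 with pandas 2.3.3 read the table. Because background was not subtracted, folds of dim genes are understated. A gene at or below the threshold on both arrays of a group has a bound there: its fold is written as "at least", against the higher of its own value and the lowest value above the threshold. Trial fits of the same design were run before the final one.

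The 23 gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01, then an estimated one) and fry, which asks whether a list's genes move, on balance, 1 way. A list's median was also set against 10000 random lists of its size matched on mean intensity. Their genes were drawn independently, so their range is too narrow where the genes of a list vary together. The respiratory chain list was selected by symbol pattern, which left out Cox4i1 and took in some assembly factors. The rule for named genes, also fixed before, took Lin28a and Lin28b, up to 12 genes per direction (those with an adjusted p under 0.05 first, then by smallest p at an absolute log2 fold change of 0.5 or more), up to 4 members per list and the sex-linked genes. Rows named only by a locus or model number were left out of it, a reading settled after 2 such rows had been seen near the top.

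The fit was tested on simulated data for this comparison: 20 runs on 7779 independent genes with 200 changed. It called 86.3% of genes changed by a log2 fold of 1 and 96.9% of those changed by 2, with 9.2 false calls per run on average. Of unchanged genes 4.94% had p under 0.05. Genes in the simulation do not vary together and no array stands apart, so it tests neither the preset correlation nor an array such as wild-type replicate 1. The shares called hold for 200 changed genes. With fewer changed genes the adjustment is stricter and a smaller share would be called.

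Alternatives were log2 of intensity plus 16, no filter, a stricter filter (92.6 on all 4 arrays), every row kept, eBayes with trend and robust, the replicate number as a block, an adjusted p under 0.10, an estimated correlation, and leaving out each array in turn. Normexp background correction with offsets of 16 and 50 was added after the data were examined. No reference genome was used, so the planned test of let-7 seed sites in 3′ untranslated regions was not run and no coordinates are given.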

Results

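The study measured messenger RNA in quadriceps muscle of male mice that carry a Lin28a transgene and of wild-type males, all CD-1 strain and 5 weeks old. Lin28a is an RNA-binding protein that blocks the maturation of the let-7 family of microRNAs. The comparison asks which muscle transcripts differ in mice labelled as carrying the transgene. There were 2 Lin28a transgenic samples and 2 wild-type samples, each hybridised as biotin-labelled cRNA to an Illumina Ref-8 bead array, on which beads carrying 1 probe sequence report a fluorescence intensity. The labels number the samples and do not say more about the animals, so p-values measure only the spread between these samples, and the number of arrays limits the precision. Of 17906 genes in the table, 7779 exceeded the background level on at least 2 of the 4 arrays and were tested. Across these genes the log2 intensities of the transgenic pair correlated at r = 0.990 and those of the wild-type pair at r = 0.978. Wild-type replicate 1 stood farthest from the transgenic arrays, at r = 0.976 and 0.978, against 0.985 and 0.989 for wild-type replicate 2.

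The label check came first. The Lin28a probe lay below the background threshold of 90.3 on all 4 arrays, at 86.4 and 88.0 in the transgenic samples and 82.9 and 82.6 in the wild-type samples, so no fold is given. A probe outside the part of the transcript that the transgene carries would read nothing of it, but the probe's position was not examined. The labels are therefore not checked by this probe, and expression of the transgene in these samples is not shown. Lin28b was not analysed here. The Y-linked genes Ddx3y and Eif2s3y were above the threshold on all 4 arrays and Xist was below it on all 4; all 4 samples are labelled male. Of the other Y-linked genes, Kdm5d was below the threshold on all 4 arrays and Uty was above it on 1.

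Lin28a transgenic muscle had higher intensities of collagen and other matrix genes, of genes of immature muscle and of immediate-early genes, and lower intensities of genes of the mitochondrial respiratory chain. These 4 shifts, and a lower adipocyte list, were called among 23 gene lists by limma's camera test with a preset inter-gene correlation of 0.01. With a correlation estimated from the 4 arrays every one of the 5 calls was lost, at a camera adjusted p of 0.946 for each. Unadjusted camera p was then 0.134 for respiratory chain, 0.135 for matrix, 0.159 for immature muscle, 0.249 for immediate-early and 0.381 for adipocyte. That form of the test rests on only 2 residual degrees of freedom, which limits its power. The glycolysis list, whose estimated correlation of 0.013 was near the preset one, went from camera p = 0.115 to 0.262. The rotation test fry called no list, its smallest adjusted p being 0.506. The preset correlation also called some of the same lists when the arrays were split wrongly, into 1 transgenic and 1 wild-type array on each side. The matrix list then had adjusted p = 0.0266 and 0.0151, the immediate-early list 2.28e-05 and 0.0242, the respiratory chain list 0.00557 and 0.645, and the adipocyte list 0.83 and 1.1e-08, whereas the immature-muscle list was called in neither wrong split (0.359 and 0.269). The preset-correlation p-values are too small where the genes of a list vary together between arrays, which these wrong splits show for 4 of the 5 lists.

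**Figure D1:**
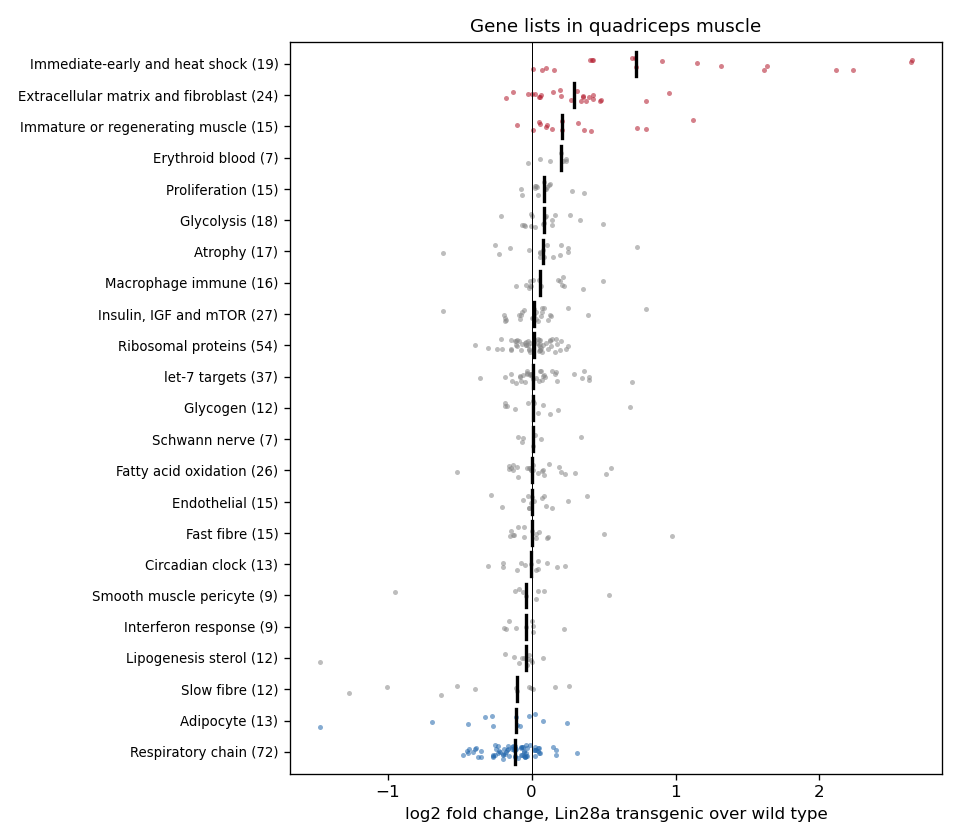
Each point is the log2 fold change of 1 gene, Lin28a transgenic over wild type (2 arrays each), and each black bar the median of its list, with the number of measured members in parentheses. Red and blue mark lists called higher and lower with a preset correlation, from the immediate-early list at a median of 0.73 to the respiratory chain at -0.12, and grey marks lists not called.

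No single gene passed an adjusted p of 0.05 with limma in either direction, and the smallest adjusted p was 0.356. At an unadjusted p under 0.05 there were 394 genes higher and 299 lower in transgenic muscle, 693 in all, where chance alone gives about 389. Without transgenic replicate 1 these counts were 210 and 167. Both transgenic arrays lay above both wild-type arrays for 1695 genes (21.8%) and below them for 1298 (16.7%), against a chance share of 16.7% in each direction. A log2 fold change of 1 or more was seen for 17 genes higher, 16 of them without overlap between the groups, and for 21 genes lower, 10 of them without overlap. Of the 21 lower genes, 15 were at least 2-fold brighter on wild-type replicate 1 than on every other array. Without that array the counts were 16 higher and 14 lower. The median standard error of a log2 fold change was 0.08.

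Among genes with the smallest p and higher intensity, several build or bind the extracellular matrix. Col5a1 was 1.94-fold higher (log2 0.95, SE 0.10), Col1a1 1.74-fold (log2 0.80, SE 0.10), the secreted matrix protein gene Spon2 2.40-fold (log2 1.26, SE 0.18) and the thrombospondin gene Thbs2 1.42-fold (log2 0.50, SE 0.08). The gene with the smallest p was Hmgn3, which encodes a nucleosome-binding protein, at 303.5 ± 4.33 in transgenic and 136.9 ± 7.78 in wild-type muscle (mean ± SD, n = 2 each). Bcat1, a branched-chain aminotransferase and a let-7 target, was 1.63-fold higher (log2 0.70, SE 0.07). The chemokine gene Cxcl1 was 2.62-fold higher (log2 1.39, SE 0.20), the matricellular gene Ccn1 1.62-fold (log2 0.70, SE 0.08), and the immediate-early gene Ier3 was at log2 0.72 (SE 0.09). The carbonic anhydrase gene Car14 was 1.53-fold higher and the selenoprotein gene Selenon 1.43-fold. The aldehyde dehydrogenase gene Aldh3a1 was below the background threshold in both wild-type samples and at least 1.72-fold higher in transgenic muscle. All 12 had an adjusted p between 0.356 and 0.486, so none passed the test.

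Among genes with a symbol and lower intensity, Gsn, which encodes the actin-severing protein gelsolin, had the smallest p, at 300.4 ± 9.32 in transgenic and 502.8 ± 25.1 in wild-type muscle (mean ± SD, n = 2 each). The log2 difference was -0.74 (SE 0.07). Inmt, an N-methyltransferase gene, differed most among the 12 named, at a log2 fold change of -1.97 (SE 0.39), and at -1.50 to -2.44 with any 1 array left out; genes bright on wild-type replicate 1 alone, such as Mup3 at -2.47, had larger differences. Apoe was at -0.78 (SE 0.24), and at -0.45 without that array. Myoc was at -0.72 and Clec2d at -0.68, and without transgenic replicate 1 at -0.42 and -0.39. The kinase inhibitor gene Camk2n1 was at -0.63, the gamma-secretase subunit gene Psenen at -0.57 and the muscle ankyrin-repeat gene Ankrd23 at -0.55. Smpdl3a was at -0.53, and at -0.39 without wild-type replicate 1. The beta-oxidation enzyme gene Echs1 was at -0.52, the receptor subunit gene Ramp1 at -0.52 and the cytochrome oxidase assembly gene Coa6 at -0.51, the last 2 at -0.29 and -0.34 without wild-type replicate 2. Adjusted p for these 12 ran from 0.476 to 0.55, so none passed. Background correction with normexp at an offset of 16, chosen after the data were examined, took the log2 fold changes of Bcat1 to 1.28, Ccn1 to 1.47, Cxcl1 to 1.99 and Inmt to -2.69.

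A shared shift of the let-7 targets was not shown. Of 73 members 37 were measured. Of these, 13 lay higher on both transgenic arrays than on both wild-type arrays (21.8% of all genes did) and 7 lay lower (16.7%). At an unadjusted limma p under 0.05, 7 members were higher and 1 lower, against 394 and 299 of all 7779 genes tested. The median log2 fold change was 0.01 and the mean 0.063, and camera gave an adjusted p of 0.259. Under the stricter filter the mean was 0.102 (camera adjusted p = 0.0556), not called. No member passed over all genes tested. Bcat1 was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0113 with limma). Igf2bp2, an mRNA-binding protein gene, was at a log2 fold change of 0.36 (SE 0.08), the cyclin gene Ccnd1 at 0.40 (SE 0.11; 0.26 without wild-type replicate 2) and the ubiquitin-conjugating enzyme gene Cdc34 at -0.36 (SE 0.08), none of them passing. With normexp, Igf2bp2 was at 0.69 and Cdc34 at -0.58. The insulin, IGF and mTOR list of 27 genes had a median of 0.02 (adjusted p = 0.804).

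Genes of immature or regenerating muscle were higher in transgenic samples. Of 15 measured members, 14 had a positive log2 fold change and 12 lay above both wild-type arrays on both transgenic arrays, as did 21.8% of all genes tested. The members are not independent, with an estimated inter-gene correlation of 0.248. The median was 0.21 against a range of -0.06 to 0.07 in 95% of random lists matched on intensity, with a camera adjusted p of 7.88e-05 (adjusted p = 0.946 with an estimated correlation). Igf2, a fetal growth factor gene, was 1.73-fold higher (log2 0.79, SE 0.21) and Cdkn1c, a cell cycle inhibitor gene, 1.66-fold (log2 0.73, SE 0.19). Without transgenic replicate 1 both were at a log2 fold change of 0.49. Chrna1, a subunit of the acetylcholine receptor, was at a log2 fold change of 0.36 (SE 0.07) and Myh8, the perinatal myosin heavy chain, at 0.32 (SE 0.08), both at 0.76 with normexp. No member passed, over all genes or adjusted over the list alone. The list's mean stayed between 0.21 and 0.39 when any 1 array was left out, and the call was kept each time.

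**Figure D2:**
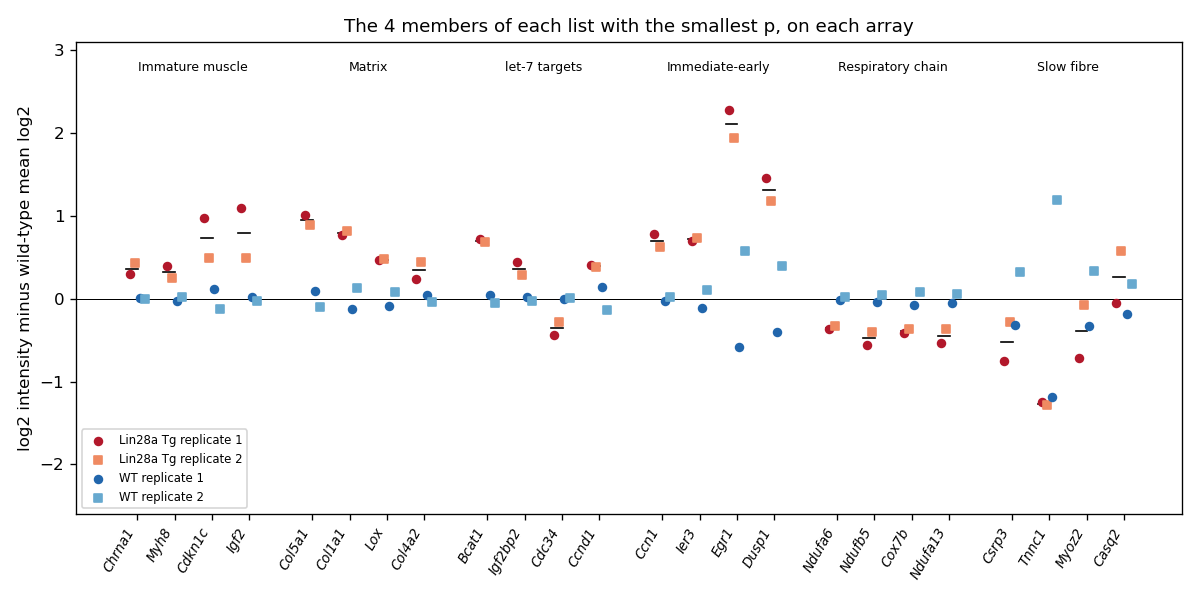
The vertical axis gives log2 intensity minus the wild-type mean of log2 intensity, for the 4 members of each of 6 lists with the smallest p, with 1 point per array and a short black bar at the transgenic mean. In the immature-muscle and matrix lists both transgenic points lie above both wild-type points for the genes shown, which choice by smallest p favours. Over all measured members this held for 12 of 15 and 13 of 24. Egr1 and Dusp1 also differ between the wild-type arrays, and Tnnc1 is high on wild-type replicate 2 alone.

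The list of matrix and fibroblast genes was called higher as well, and its collagens and lysyl oxidases rose more than 6 other members chosen for comparison. Of 24 measured members, 21 had a positive log2 fold change, 13 lay above both wild-type arrays on both transgenic arrays and 0 lay below. The median was 0.29 (matched random lists -0.07 to 0.09; camera adjusted p = 8.85e-06, and adjusted p = 0.946 with an estimated correlation). Adjusted over the list alone, 3 genes passed with limma, namely Col5a1, Col1a1 and the collagen cross-linking enzyme gene Lox (log2 0.47, SE 0.08). No member passed over all genes. Collagens and lysyl oxidases of the list had a mean log2 fold change of 0.39 (SD 0.27, 12 genes), and 6 other genes of the list that fibroblasts express (Dcn, Lum, Mfap5, Mmp2, Pdgfra and Thy1) one of 0.04 (SD 0.13). The second mean was 0.21 without wild-type replicate 1, 0.12 without transgenic replicate 2, -0.04 without transgenic replicate 1 and -0.12 without wild-type replicate 2. That division was made after the values were seen, and some members were in neither set. These were Fstl1 at 0.483, Timp1 at 0.425, Fbn1 at 0.38, Bgn at 0.272, Sparc at 0.021 and Fmod at -0.131. The list's mean of 0.27 was 0.17 without wild-type replicate 2.

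Respiratory chain genes were lower by a small amount. Of 72 measured members, 58 had a negative log2 fold change, 35 lay below both wild-type arrays on both transgenic arrays and 4 lay above. The median was -0.12, a fold of 0.922, against -0.05 to 0.03 in matched random lists (camera adjusted p = 4.72e-09, and adjusted p = 0.946 with an estimated correlation). The complex I subunit genes Ndufa6, Ndufb5 and Ndufa13 were at log2 fold changes of -0.35 (SE 0.06), -0.48 (SE 0.08) and -0.45 (SE 0.09), and the cytochrome oxidase subunit gene Cox7b at -0.39 (SE 0.08), which was -0.76 with normexp. No member passed, over all genes or adjusted over the list alone. The list's mean of -0.13 was -0.09 without wild-type replicate 2. That array also had the highest slow-fibre score, the mean deviation of slow-fibre genes from their means over all arrays, at 0.82, against 0.15 for transgenic replicate 2, -0.45 for transgenic replicate 1 and -0.52 for wild-type replicate 1.

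Other metabolic lists were not called. Glycolysis genes had a median log2 fold change of 0.08 (18 genes, adjusted p = 0.259), fatty acid oxidation genes 0.00 (26 genes, 0.804), glycogen genes 0.01 (12 genes, 0.804) and lipogenesis and sterol genes -0.04 (12 genes, 0.259). Within the glycogen list, the glycogen-binding protein gene Stbd1 was 1.61-fold higher (log2 0.68, SE 0.11) and passed adjusted over the list alone (adjusted p = 0.0315 with limma). Within the fatty acid oxidation list, Pdk4, a kinase that inhibits pyruvate dehydrogenase, was at 0.52 (SE 0.10) and Echs1 at -0.52 (SE 0.11), neither passing. Leaving out 1 array made 2 of these lists a call, fatty acid oxidation without transgenic replicate 1 (mean 0.15) and lipogenesis without transgenic replicate 2 (-0.37) or wild-type replicate 2 (-0.29).

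Immediate-early and heat-shock genes were higher on the transgenic arrays, and wild-type replicate 1 weighed most in this. All 19 measured members had a positive log2 fold change, 12 of them without overlap between the groups, and the median was 0.73 (matched random lists -0.07 to 0.10; camera adjusted p = 1.94e-07, and adjusted p = 0.946 with an estimated correlation). Adjusted over the list alone, 4 genes passed with limma: Ccn1, Ier3, the transcription factor gene Egr1 (4.32-fold, log2 2.11, SE 0.42) and the phosphatase gene Dusp1 (2.49-fold, log2 1.32, SE 0.29). None passed over all genes. The list's score was 0.48 and 0.58 on the transgenic arrays, 0.10 on wild-type replicate 2 and -1.15 on wild-type replicate 1. Its mean log2 fold change of 1.05 was 0.43 without wild-type replicate 1 and 1.67 without wild-type replicate 2, the call being kept in both.

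Markers of other cell types in muscle were examined for differences between the groups. The adipocyte list was called lower, with a median of -0.11 (13 genes, adjusted p = 0.0316, and adjusted p = 0.946 with an estimated correlation), but its scores did not separate the groups, at -0.48 and 0.22 on the transgenic and 0.35 and -0.08 on the wild-type arrays. Its mean of -0.26 was 0.09 without transgenic replicate 1, -0.05 without wild-type replicate 1, -0.61 without transgenic replicate 2 and -0.48 without wild-type replicate 2, and the call was lost in the first 2 of these. With normexp the mean was -0.45 (adjusted p = 0.00445), and under the stricter filter it was -0.35 and not called. Macrophage and immune genes had a median of 0.06 (16 genes, camera adjusted p = 0.0711), with 10 members positive and 6 negative. Cd74 (log2 0.49, SE 0.06) and C1qb (log2 0.35, SE 0.06) passed adjusted over the list alone. The related genes C1qa and C1qc were at 0.05 and 0.01. Endothelial genes had a median of 0.00 (15 genes, adjusted p = 0.896), smooth muscle and pericyte genes -0.04 (9 genes, 0.843), Schwann cell and nerve genes 0.01 (7 genes, 0.843) and erythroid genes 0.21 (7 genes, 0.259). The macrophage list became a call without wild-type replicate 2 (mean 0.15), and the erythroid list without transgenic replicate 1 (0.40) or wild-type replicate 1 (0.36).

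Muscle fibre and growth lists were not called either. Slow-fibre genes had a median log2 fold change of -0.10 (12 genes, adjusted p = 0.259) and a mean of -0.97 without wild-type replicate 1 and -0.60 without transgenic replicate 2, either of which made the list a call. The mean was 0.00 without transgenic replicate 1 and 0.37 without wild-type replicate 2, where the direction turned. Fast-fibre genes had a median of 0.00 (15 genes, adjusted p = 0.804), atrophy genes 0.08 (17 genes, 0.641), proliferation genes 0.09 (15 genes, 0.0635), ribosomal protein genes 0.02 (54 genes, 0.804), interferon-response genes -0.04 (9 genes, 0.259) and circadian clock genes 0.00 (13 genes, 0.804). Leaving out 1 array made a call of the atrophy list (without transgenic replicate 1, mean 0.26), the proliferation list (without wild-type replicate 1, 0.09) and the interferon list (without wild-type replicate 2, -0.14). For the glycogen, ribosomal protein, fast-fibre and Schwann cell lists the median and the mean were above 0 while the test pointed down.

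Many transcripts abundant in liver, though not all, read higher on wild-type replicate 1 than on the other arrays, and some read far higher. Apoa2, an apolipoprotein gene, read 5506 on that array and 84.9 to 89.9 on the other 3, Mup3, a major urinary protein gene, 3307 against 84.9 to 97.6, and Ttr, the transthyretin gene, 1746 against 80.3 to 83.2. These genes were singled out after their values were seen. On wild-type replicate 1, 55 genes were at least 2-fold brighter than on every other array, against 2, 4 and 8 such genes on transgenic replicate 1, transgenic replicate 2 and wild-type replicate 2. Most liver genes fell below the threshold on the other arrays and were not tested, and 32 of the 101 hepatocyte genes examined were among the genes tested. Without wild-type replicate 2, which leaves this array as the only wild-type sample, limma called 3 genes higher (Pdrg1, Egr1 and Jun) and 16 lower, and all 16 were at least 2-fold brighter on wild-type replicate 1 than on every other array.

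**Figure D3:**
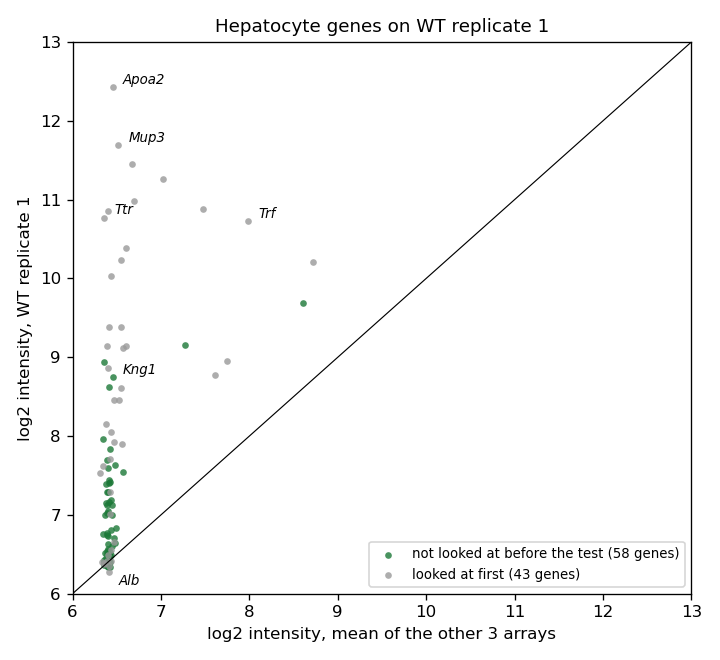
Each point is 1 hepatocyte gene, with its log2 intensity on wild-type replicate 1 on the vertical axis and its mean log2 intensity on the other 3 arrays on the horizontal axis, and the line marks equal values. Most points lie above the line, Apoa2 and Mup3 highest, while Alb lies at background on all 4 arrays.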

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

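Normexp correction and the level-based filters were chosen after the data were seen. Under all 10 alternatives other than leaving out an array, no gene was called in either direction where genes were tested, and none of the 110 genes followed by the naming rule changed sign, although only 96 of them passed the stricter filter. The neqc, median-shift, slide-block and seed-site alternatives were not run. The trend and robust setting does not enter camera and so says nothing about the lists. Unadjusted p-values under 0.05 rose to 647 genes higher and 510 lower with no filter, as more genes were tested. The proliferation list became a call with no filter (mean log2 fold change 0.058), at an adjusted p under 0.10 (0.087) and with normexp at offset 16 (0.19) or 50 (0.11). The macrophage list became one with every row kept (0.11) and at an adjusted p under 0.10 (0.11). The adipocyte list was lost under the stricter filter (-0.35) and called at a larger mean with normexp at offset 16 (-0.45). The causes of these changes of list calls were not tested, except that a looser threshold admits more. With an estimated correlation the calls were lost at unchanged means, while both the correlation and the degrees of freedom of the test differ. These means were -0.13 for respiratory chain, 0.30 for immature muscle, 0.27 for matrix, -0.26 for adipocyte and 1.05 for immediate-early.

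Whether the replicate numbers pair the samples cannot be settled. Deviations of same-numbered arrays correlated at 0.037 across genes, but within groups of 2 the second pair mirrors the first. Slow-fibre scores moved with the number, at -0.45 (transgenic) and -0.52 (wild type) for replicate 1 and 0.15 and 0.82 for replicate 2. Atrophy scores did so too (-0.17 and -0.18, then 0.23 and 0.12), whereas adipocyte scores did not (-0.48 and 0.35, then 0.22 and -0.08). With the number as a replicate block, 0 genes were called, 384 were higher and 272 lower at an unadjusted p under 0.05, and the adipocyte list was no longer called (-0.26); no other call changed.

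Leaving out each array in turn leaves 1 array in a group, which is then assumed to vary like the others. Genes called ranged from 0 to 3 higher and 0 to 16 lower, and Egr1 was called without wild-type replicate 2 (log2 2.69). Genes at an unadjusted p under 0.05 ranged from 210 to 344 higher and 167 to 321 lower. Means of lists whose call changed ranged from -0.61 to 0.086 for adipocyte (0.086 without transgenic replicate 1, a change of sign), -0.075 to 0.15 for fatty acid oxidation, -0.14 to 0.26 for atrophy, -0.10 to 0.40 for erythroid, -0.37 to 0.04 for lipogenesis, -0.97 to 0.37 for slow fibre, 0.07 to 0.10 for proliferation, 0.074 to 0.15 for macrophage and -0.14 to 0.044 for interferon response. Changes of sign between settings in which a list was never called are not counted here. Signal over background limits dim genes: 10127 of 17906 genes did not exceed the threshold on 2 arrays and were not tested.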

Other observations

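The tests on ribosomal protein genes, on fibroblast markers, on leaving out single arrays and on other splits were chosen after the results they bear on were seen. The bounds for single arrays, fibroblast markers, imprinted genes and heat-shock members were tightened after their values were known. The liver hypothesis came from the data, but the genes of its test had not been looked at before. Intervals in this section are 95% bootstrap intervals over the genes of a set. They do not measure the spread between samples, and they are too narrow where the genes of a set vary together.

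The immature-muscle list holds 5 measured imprinted genes, which did not move alike and of which none passed the test. Igf2 (log2 0.79), Cdkn1c (0.73) and the noncoding RNA gene H19 (0.41, SE 0.21; 0.12 without transgenic replicate 1 and 0.71 without transgenic replicate 2) were higher, Dlk1 was at -0.10 (-0.26 with normexp), and Mest, below the background threshold in both wild-type samples, was at least 1.05-fold higher. A shared rise of imprinted genes was tested on 9 measured imprinted genes outside all lists, with 22 others not measured. The mean log2 fold change of the 9 was 0.041 (95% bootstrap interval -0.075 to 0.19), against 0.39 for the 5 list members. The mean of the list members was 0.19 without transgenic replicate 1 and 0.58 without transgenic replicate 2. Of the 9, 4 failed the stricter threshold, where folds are understated, and the other 5 had a mean of 0.07 with an interval of -0.13 to 0.34, whose upper end passes 0.19, the 50% mark of the list members' mean, so a shared rise is neither shown nor excluded. Among the 9, Grb10 was at 0.54 (SE 0.22) and was picked out after its value was seen.

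For the 693 genes at an unadjusted p under 0.05, only 3 splits of the arrays into 2 and 2 exist, of which 1, the real one, gave as many, the highest other split giving 340. That is too few splits for a share under 0.05.

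For the lower respiratory chain genes, a shift of all bright genes was not seen in the deposited values. Random lists matched on intensity had medians mostly from -0.05 to 0.03, and none was as low as -0.12 (percentile 0). The test decides little, because the arrays had already been normalized to each other, which leaves little room for such a shift. The percentile does not measure how unusual the list is, since the random genes were drawn independently. A poorer recovery of short transcripts stays open. The ribosomal protein genes had a median of 0.017 (interval -0.03 to 0.06), but transcript length was not compared within either list. A smaller share of slow, oxidative fibres stays open: with the slow-fibre score as a covariate the median was -0.10 (interval -0.13 to -0.06), and the upper end did not clear the bound. A transgene effect is an open hypothesis, since the list is called only with the preset correlation.

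For the higher matrix genes, more fibroblasts stay open. The 6 fibroblast genes chosen for comparison lay below the collagens and lysyl oxidases by a log2 difference of -0.35 (interval -0.53 to -0.18). With any 1 array left out the difference was -0.26 to -0.43, each interval below 0. Members of the list in neither set did not enter this comparison. For the 3 of them that are not structural matrix proteins, Mmp2, Pdgfra and Thy1, the difference was -0.28, but -0.17 without transgenic replicate 2, where the interval of -0.35 to 0.00 reaches the bound. A single deviating array cannot be told apart from a group difference: the lowest mean with 1 array left out was 0.17, without wild-type replicate 2, and its interval of 0.05 to 0.30 spans the bound. A change in matrix production with the transgene is an open hypothesis.

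On wild-type replicate 1, of 58 hepatocyte genes not looked at before, 50 (86.2%, interval 77.6 to 94.8) had their highest value of the 4 arrays, against 22.5% of all genes, and 12 were at least 2-fold above the mean of the others; liver RNA in that sample may be the source, although how it came there was not tested. The 43 genes looked at first gave 38, and 3 of the 58 and 10 of the 43 were above background on all 3 other arrays. Against it, Alb (77.7), Apoh (85.1), Fgb (83.6) and Fabp1 (84.8), abundant in liver, stayed at background there, and without a liver sample unresponsive probes cannot be excluded. The immediate-early difference may come largely from this array, since its mean of 1.05 was 0.43 (interval 0.12 to 0.74) without it. A heat-shock response in the transgenic samples stays open: the 4 heat-shock members averaged 1.42 (interval 0.41 to 2.44) on all arrays, but 0.21 (interval -0.21 to 0.62) without wild-type replicate 1, where 2 of them turned negative, and 0.95 (interval -0.12 to 2.02) without transgenic replicate 2.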
